A study of Sus scrofa with 24 samples.

How the data were processed

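RNA of 24 heart muscle samples from 9 domestic pigs was hybridized to 1-colour Agilent porcine arrays, 1 array per sample. Per the labels, every RNA sample had an RNA integrity number above 6 and 100 ng of total RNA was labelled. The arm, pig and region of each array were taken from the labels, which mark the arrays of pigs 10, 18 and 40 as not treated; these pigs are taken as the medium placebo arm. The groups are 3 border, 3 infarct and 2 normal region arrays with medium, and 6, 6 and 4 with secretome.

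The deposited scanner files hold intensity values per spot: a processed signal that is background-subtracted and detrended by Agilent Feature Extraction 10.7.3.1 per the file headers, mean and background signals, and flags. The deposited table of the series holds log2 values that the authors normalized between arrays, with limma 3.14.4 named in the labels; the method, offset and filter are not given in the sources used here. Its 24 column medians lie between 7.684 and 7.692. It covers 33348 probes, 26221 of them kept here, and each of its 24 columns matched its own array best, with correlations of 0.899 to 0.932. Its scale is log2 and its columns are centred on a common level, and which scaling gave that level stays unknown. It served as an alternative only.

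Spots flagged as non-uniform or population outliers were left out, 1 to 27 per array, and the spots of a probe were averaged. The processed signal was scaled to the 75th percentile of each array and put on the log2 scale. A probe was kept when well above background on at least 3 of 24 arrays, which left 34360 probes. Gene symbols came from RefSeq accessions (9197 probes), gene IDs (1498) and names in the array files (4129): 14824 probes had 1 symbol, 10 had several and 28769 had none. Of the kept probes 13599 had 1 symbol, covering 6376 genes, each read from its brightest kept probe. COL3A1 and CD68 had no usable probe, and the MYH6 and COL1A1 probes were named from descriptions in the array files. For genes below background in a whole group only a bound is given, written as at least N-fold.

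Linear models with a mean per region and arm were fitted in limma 3.58.1 (R 4.3.3, statmod 1.5.0, version 1.17.8 of data.table), with pig as a random block (correlation 0.548) and moderated t tests. Region comparisons give both arms equal weight, and a probe passed at a Benjamini-Hochberg adjusted p under 0.05. Of 36 fixed gene lists, the 33 with at least 5 measured members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. List scores, the mean of the members on an array, were compared by exact permutation of arms over pigs or exact sign-flip within pigs. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

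The groups, comparisons, lists, named genes and most alternatives were chosen before the data were examined; later additions are named in the closing section. Genes are named by rule. In each region comparison these are the 10 highest and 10 lowest log2 fold changes that pass with the same direction in every pig with both regions. Where fewer than 5 pass, up to 5 with the smallest p are named and stated as not past. The 4 members with the smallest p of each list described and 15 fixed genes are added, and 83 genes came from the first and last parts.

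Pairing was checked by correlating probe deviations: 21 pairs from the same pig averaged 0.583, and all 21 were above 0.1. Arrays fell in 2 scan series and on 6 slides, so alternatives with each as a block were fitted. All arrays of a pig share a scan series, where pairs of different pigs and groups averaged 0.439 (highest 0.705). Values above 0.1 therefore do not tell a shared pig from a shared scan series. With scan series as a covariate the pig block correlation was 0.204. No 2 arrays were identical, with correlations of 0.8143 to 0.9912. Between 61.5% and 75.6% of probes lay well above background on an array, and the spike-in fit had an r2 of 0.993 to 0.998.

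The number of arrays limits the precision. In simulated data with 200 changed probes per comparison, limma recovered 120 at 2-fold between infarct core and normal region, 122 between border zone and normal region and 145 between infarct core and border zone. For secretome against medium it recovered 12 at 2-fold and 132 at 4-fold in the infarct core, 0 and 135 in the border zone, 1 and 124 in the normal region, and 11 and 133 averaged over both regions. The list test was tested on simulated data too: a list of 20 genes raised 1.5-fold was called in 50 of 50 simulations and an unchanged list in 1. The simulated probes varied independently of each other and had no scan series. The simulations therefore do not show how often camera calls an unchanged list on these arrays.

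Alternatives were other scalings (quantile, normexp with an offset of 50, and a percentile over probes detected on all arrays), the authors' values, other probe filters, no or a fixed pig block, scan series or slide in the fit, each scan series alone, array weights, a trended robust fit, other probes of a gene and each pig left out. Probes without a symbol were tested but not named, and the magnetic resonance measurements were not used here.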

Results

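Heart muscle gene expression was measured on 24 arrays from 9 domestic pigs with a closed-chest, reperfused myocardial infarction. The pigs were treated 1 month after the infarct by percutaneous delivery into the heart muscle, and tissue was taken 1 month after treatment. Per the labels, all pigs of both arms received aspirin and clopidogrel before the infarct and in daily doses. In this set 6 pigs had received a secretome, the mixture of products released by apoptotic mononuclear blood cells, and 3 had received medium as placebo. The samples came from the infarct core, the border zone where injections were placed and a normal region away from the infarct. The secretome arm held 6 infarct core, 6 border zone and 4 normal region arrays, and the medium arm held 3, 3 and 2. Pigs 12 and 13 of the secretome arm and pig 40 of the medium arm had no normal region array. The design text gives 8 pigs per arm, so the arrays cover part of the randomized animals.

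Between 26822 and 32978 of the probes lay well above background on an array, and the 75th percentile of processed signal ranged from 210 to 617 intensity units. Both lowest values came from the border zone array of medium pig 40, with 61.51% of probes well above background. The next lowest in its scan series were 69.79% (border zone of pig 13) and 404.87 units (normal region of pig 16). The number of arrays, above all the 3 medium pigs, limits the precision of each value. The arrays were scanned in 2 series of 12. Series 1 held medium pigs 18 and 40 and secretome pigs 12, 13 and 16, and series 2 held medium pig 10 and secretome pigs 11, 14 and 15. Between arrays of different pigs and groups, the mean correlation of probe deviations was 0.44 within a scan series (94 pairs) and -0.45 across scan series (118 pairs). Values with scan series or slide as a block, and within each scan series, therefore stand beside the results. The infarct core sample of pig 40 had the lowest muscle transcripts of all: its sarcomere list score was 1.43, against 6.24 and 5.69 in the other medium infarct cores and 5.09 to 7.65 in the 6 secretome infarct cores.

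**Figure D1:**
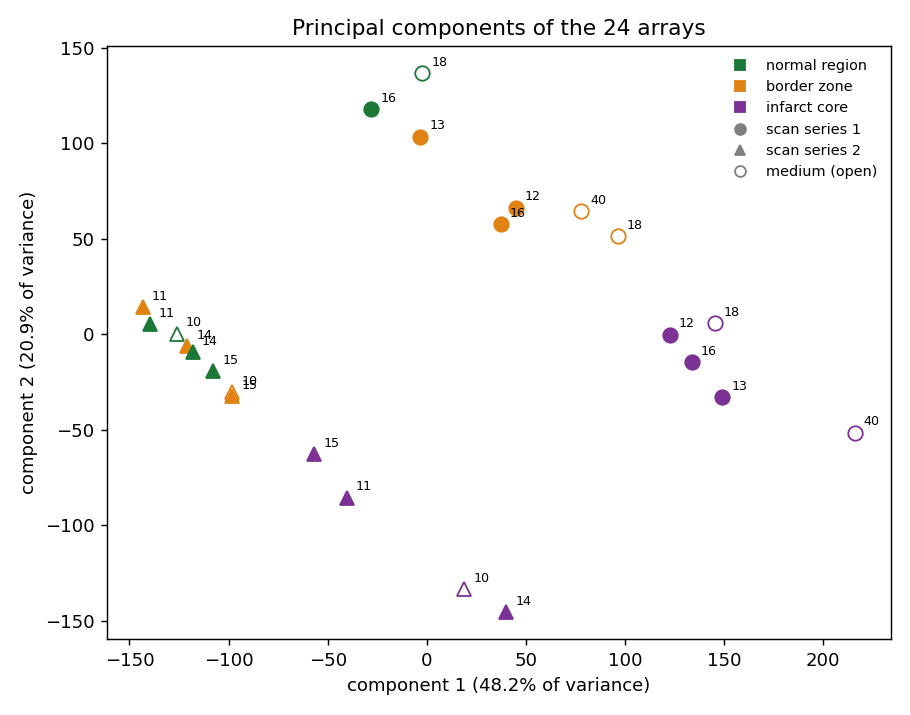
Scores of the 24 arrays on the first principal components (48.2% and 20.9% of the variance), coloured by region, shaped by scan series, filled for secretome and open for medium, with pig numbers. Arrays part by scan series, and within each scan series the infarct core arrays lie apart from the rest. Border zone and normal region arrays overlap in part. The infarct core of pig 40 lies farthest to the right.

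The first comparison asks how the infarct core differs from the normal region, with both arms given equal weight (9 and 6 arrays). The infarct core had far more transcripts of scar matrix and of macrophages, and far fewer of muscle contraction and of mitochondrial energy supply. Collagen type XI alpha 1 (COL11A1), a chain of a fibril-forming collagen, was higher by 6.76 ± 0.63 on the log2 scale (SE), and aggrecan (ACAN), a cartilage proteoglycan, by 6.63 ± 0.66. Among the lower genes, ATP2A2, the calcium pump of the sarcoplasmic reticulum, fell by 2.60 ± 0.36 and myoglobin (MB), the oxygen store of muscle, by 3.0 ± 0.54. In limma 8718 of 34360 probes passed as higher and 9489 as lower, which covers 1767 and 1963 of 6376 named genes. Among the called genes 911 were more than 2-fold higher and 846 more than 2-fold lower.

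Of the fibrillar collagen and scar matrix list, 28 of 28 measured members rose in the infarct core, by 3.43 on the log2 scale on average (3.69 within scan series 1 and 3.52 within scan series 2). Fibronectin (FN1), which links cells to matrix, rose by 4.61 ± 0.40, versican (VCAN), a large matrix proteoglycan, by 3.26 ± 0.31, and tenascin C (TNC), a matrix protein of healing wounds, by 5.91 ± 0.58. Camera gave the list an adjusted p of 9.27e-15, and adjusted p = 0.307 with an estimated correlation. Periostin (POSTN), made by activated fibroblasts, rose by 4.54 ± 0.53 (limma adjusted p = 1.1e-06). The probe named COL1A1 from its file description went the other way, at -0.62 ± 0.15 (limma adjusted p = 0.00117), unlike the 28 list members that rose. Of 24 matrix proteases and inhibitors 19 rose and 2 fell, with cathepsin K (CTSK), a collagen-degrading protease, up by 2.87 ± 0.25 and urokinase (PLAU), the activator of plasminogen, up by 1.51 ± 0.16. That list passed camera at adjusted p = 8.67e-06, with adjusted p = 0.307 with an estimated correlation.

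The other genes with the highest rises were COLL11A1, a further collagen XI symbol (at least 102-fold higher), CRABP1, a binding protein for retinoic acid (6.20 ± 0.91), C1QTNF3, a secreted relative of complement C1q (6.13 ± 0.66), tenomodulin (TNMD), a tendon protein (at least 41.1-fold), CTHRC1, a collagen-associated secreted protein (5.68 ± 0.54), pleiotrophin (PTN), a heparin-binding growth factor (5.44 ± 0.48), and fibromodulin (FMOD), a regulator of collagen fibrils (at least 35.4-fold). All 10 rose in 6 of 6 pigs that had both regions. The lower end held CCK, the precursor of cholecystokinin, which fell by 4.67 ± 0.50, then TARSL2 (-3.60 ± 0.48), FRMD5 (-3.48 ± 0.48), CDHR1 (-3.48 ± 0.46) and ASB15 (-3.45 ± 0.51). It also held COX8H, a heart subunit of cytochrome oxidase (-3.37 ± 0.64), EYA4, a transcription cofactor (at least 6.57-fold lower), myomesin 2 (MYOM2), a protein of the sarcomeric M band (-3.26 ± 0.55), FITM1, which acts in lipid droplet formation (-3.23 ± 0.51), and PLIN5, a lipid droplet coat protein of oxidative tissue (-3.20 ± 0.47). All 10 fell in 6 of 6 pigs.

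**Figure D2:**
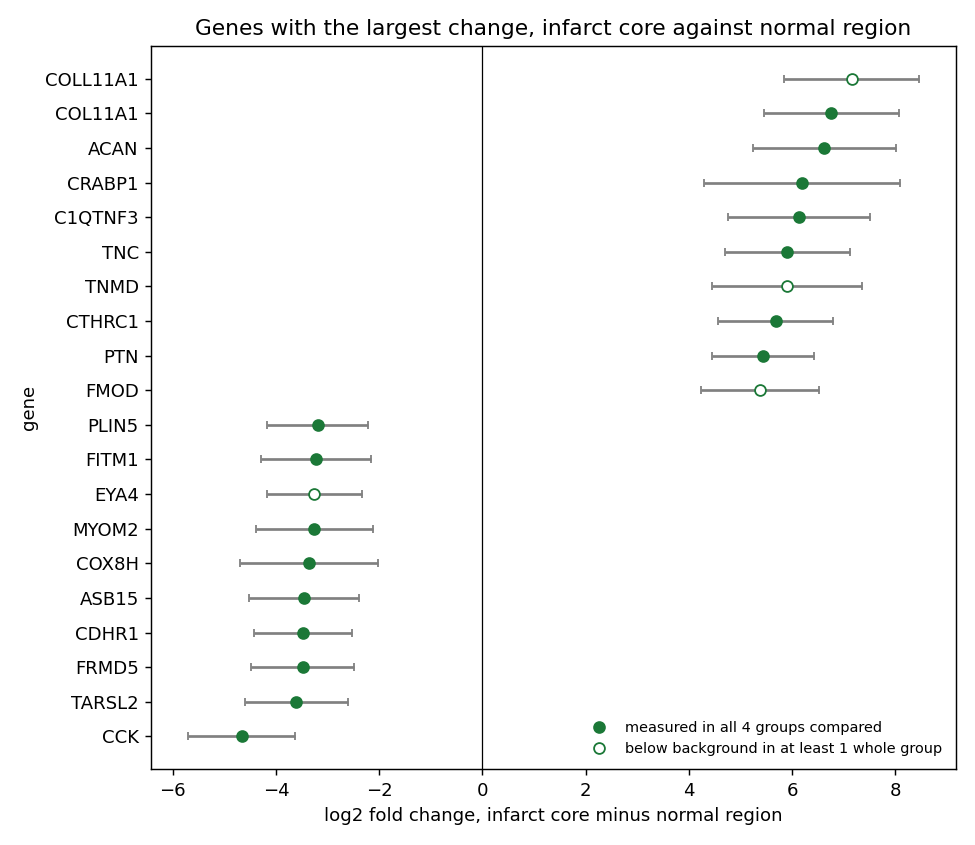
Log2 fold change of 20 genes between infarct core and normal region, with 95% confidence intervals as bars, averaged over both arms. Open points mark genes below background in a whole group, for which only a bound is given: COLL11A1, TNMD, FMOD and EYA4.

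Of the sarcomere and calcium handling list, 19 of 19 members fell, by 2.18 on average (-2.83 within scan series 1, -1.54 within scan series 2 and -1.70 without pig 40). SLC8A1, the sodium-calcium exchanger, fell by 1.33 ± 0.19. Cardiac alpha myosin (MYH6) fell by 2.58 ± 0.57 and beta myosin (MYH7), the main ventricular form, by 1.13 ± 0.39 (limma adjusted p = 0.0198, and 0.102 with pig as a fixed block), or 0.66 without pig 40. Camera gave the sarcomere list an adjusted p of 1.58e-05, and adjusted p = 0.404 with an estimated correlation. The muscle transcripts of the pig 40 infarct core, a score of 1.43, move with this group.

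Energy genes fell as groups. All 23 fatty acid oxidation genes fell (mean -2.02), among them DECR1, which handles unsaturated fatty acids (-1.45 ± 0.18), PDK4, an inhibitor of pyruvate dehydrogenase (-2.31 ± 0.29), and HADHA, of the mitochondrial trifunctional protein (-2.11 ± 0.28). All 17 TCA cycle and ketone genes fell (mean -2.03), with PDHB, a subunit of pyruvate dehydrogenase, at -1.84 ± 0.21 and SUCLG1, of succinyl-CoA ligase, at -2.13 ± 0.25. All 16 oxidative phosphorylation genes fell (mean -1.97), with SDHB of complex II at -1.99 ± 0.23. Camera gave these lists adjusted p of 4.84e-09, 1.96e-08 and 8.59e-08, and each had adjusted p = 0.307 with an estimated correlation. Within scan series 1 and 2 their means were -2.47 and -1.73, -2.44 and -1.78, and -2.32 and -1.69; the muscle loss of pig 40 moves with them, and without that pig they were -1.85, -1.89 and -1.80.

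Of 17 macrophage and monocyte genes 16 rose (mean 1.73, and 2.07 and 1.59 within scan series 1 and 2), led by lysozyme (LYZ), an antibacterial enzyme of phagocytes (5.20 ± 0.43), AIF1, an actin-binding protein of macrophages (1.92 ± 0.21), and CD86, a costimulatory ligand (1.44 ± 0.16). Of 35 inflammatory cytokine and signalling genes 23 rose and 1 fell (mean 1.16), among them the chemokines CXCL14 (4.99 ± 0.41) and CCL19 (2.12 ± 0.25) and MYD88, an adaptor of Toll-like receptors (1.40 ± 0.15). Camera gave these lists adjusted p of 2.19e-07 and 2.40e-05, each with adjusted p = 0.307 with an estimated correlation. Caspase 1 (CASP1), which matures interleukin 1 beta, rose by 1.71 ± 0.20 and IL1B itself by 1.63 ± 0.38, while TNF had a log2 difference of -0.07 ± 0.24. VEGFA, the vascular growth factor, fell by 1.88 ± 0.18, MEF2C, a muscle transcription factor, fell by 0.71 ± 0.21 (short of the threshold without pig 18, limma adjusted p = 0.0652), and the endothelial adhesion molecule PECAM1 differed by -0.05 ± 0.15. The natriuretic peptide NPPB rose by 2.57 ± 1.03 (limma adjusted p = 0.0404, 0.0875 with scan series as a covariate, 0.0970 with slide as a block and 0.0611 with pig as a fixed block). It was 1.11 without pig 10 (0.495) and fell short without pig 11 (0.0759), 13 (0.0548), 14 (0.069) or 16 (0.0645). NPPA differed by 1.02 ± 0.88 (limma adjusted p = 0.344), and by 1.78 without pig 40 (0.0358). The probes of smooth muscle actin (ACTA2) disagree: the brightest fell by 0.94 ± 0.28, and 4 of 6 others were higher by 2.18 to 2.64.

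With 1 score per array, all 8 lists above kept the direction in 6 of 6 pigs, with an exact sign-flip p of 0.0312, the smallest that 6 pigs allow, and 0.0448 adjusted over the lists. No list held with an estimated correlation, and limma's probe count was 9719 within scan series 2 alone and 14660 within scan series 1 alone.

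**Figure D3:**
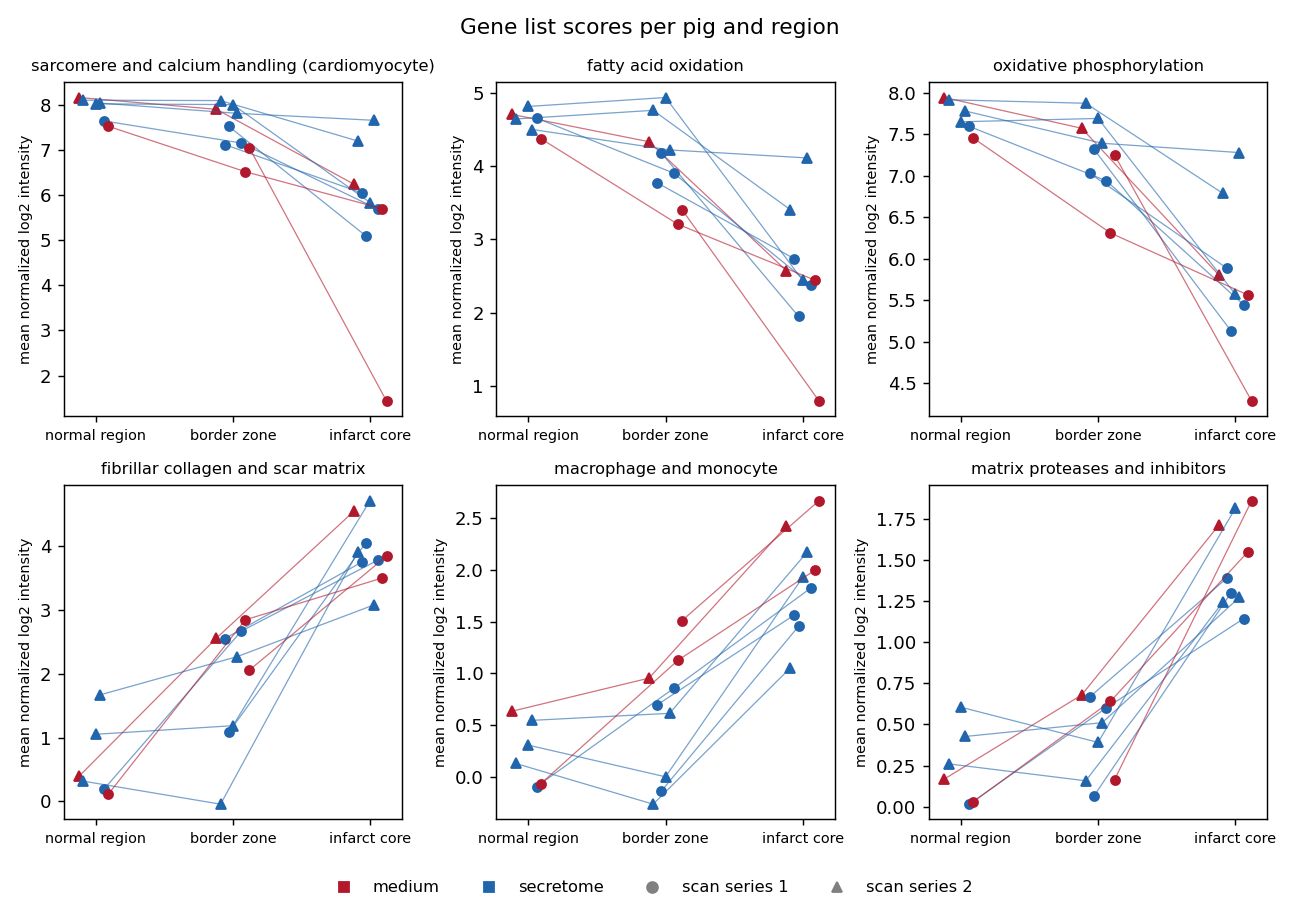
Mean normalized log2 intensity of 6 gene lists in the normal region, border zone and infarct core, 1 point per array and 1 line per pig, coloured by arm and shaped by scan series. Between normal region and infarct core the 3 muscle lists fall and the collagen, macrophage and protease lists rise in each of 6 pigs, and pig 40 has the lowest sarcomere score, 1.43.

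The next comparison asks what marks the border zone, the injected tissue around the infarct, against the normal region (9 and 6 arrays). The border zone carried more scar matrix transcripts: 8 of 28 fibrillar collagen and scar matrix genes rose over all probes and 25 of 28 adjusted over the list alone, by 1.55 on average (2.19 within scan series 1 and 1.15 within scan series 2). Tenascin C rose by 3.23 ± 0.58, fibronectin by 2.11 ± 0.40, CILP, a matrix protein of cartilage, by 3.08 ± 0.59, and COMP, which binds collagen fibrils, by 2.54 ± 0.49. Limma called 157 of 34360 probes higher and 3 lower, which covers 39 genes higher and 1 lower. Camera gave the scar list an adjusted p of 7.1e-24, and adjusted p = 0.363 with an estimated correlation; its score was higher in 5 of 6 pigs, with an exact sign-flip p of 0.0938 and 0.375 adjusted over the lists.

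Genes past the threshold and higher in 6 of 6 pigs were pleiotrophin (3.03 ± 0.48), fibromodulin (at least 4.65-fold), OLFML2B, an olfactomedin family matrix protein (2.19 ± 0.43), OSBPL6, an oxysterol-binding protein (1.19 ± 0.24), KIF15, a mitotic kinesin (at least 1.36-fold), PCDH18, a protocadherin (1.04 ± 0.23), and ELMSAN1 (0.99 ± 0.21). A second ELMSAN1 probe read -0.64 (limma adjusted p = 0.104). Periostin rose by 2.43 ± 0.53 and was higher in 5 of 6 pigs. MCHR1, a receptor for melanin-concentrating hormone, fell by 1.02 ± 0.23 (5 of 6 pigs). None of these 9 calls, nor those of TNC, FN1, CILP and COMP, held with scan series as a covariate (limma adjusted p 0.0541 to 0.120), with slide as a block (0.187 to 0.253) or with pig as a fixed block (0.557 to 0.631). Each of the 9 fell short without any 1 of pigs 10, 16, 18 and 40 (limma adjusted p 0.0583 to 0.348). So did 8 of them without pig 12 (0.0581 to 0.095, not pleiotrophin), 7 without pig 14 (0.0516 to 0.0686, not pleiotrophin or MCHR1), KIF15, MCHR1 and periostin without pig 13 (0.0586, 0.0626 and 0.0555) and MCHR1 without pig 15 (0.0555). The next lower genes, which did not pass, were HAPLN3 (-1.33 ± 0.32, past at 0.0471 without pig 11), MTG1 (-0.40 ± 0.10) and LIPE, the hormone-sensitive lipase (-1.17 ± 0.30), with limma adjusted p of 0.0662 to 0.0789; CYLC1 was too close to background for a fold. Of the fixed genes CASP1 read 0.82 ± 0.20 (limma adjusted p = 0.065), VEGFA -0.63 ± 0.18 (0.114), MYH6 -1.06 ± 0.57 (0.405) and MYH7 0.00 ± 0.39 (0.999). The fitted MYH7 value also draws on pigs without a normal region array, such as pig 40. Within the 6 pigs with both regions MYH7 was lower in the border zone in each, with differences of -0.60 to -0.02. NPPB read 2.17 ± 1.03, NPPA 0.47 ± 0.88, IL1B 0.16 ± 0.38, TNF -0.14 ± 0.24, MEF2C -0.05 ± 0.21, ACTA2 -0.07 ± 0.28, PECAM1 -0.21 ± 0.15 and the COL1A1 probe -0.25 ± 0.15, with limma adjusted p of 0.342 to 0.947.

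Other lists passed camera through small shifts of members that did not pass singly. The means were 0.45 for 17 macrophage genes, -0.45 for 17 TCA cycle genes, -0.43 for 23 fatty acid oxidation genes, -0.38 for 16 oxidative phosphorylation genes, 0.29 for 27 interferon response genes and -0.39 for 13 endothelial genes. Their camera adjusted p ranged from 0.000221 to 0.00277, and each had adjusted p = 0.587 with an estimated correlation except oxidative phosphorylation, adjusted p = 0.595 with an estimated correlation. Adjusted over the list alone, 2 macrophage genes passed, AIF1 (0.74 ± 0.21) and LYZ (1.39 ± 0.43), and no member of the other 5 lists did. Neither passed without pig 16, 18 or 40, and 5 macrophage genes did without pig 10, 11 or 13. Without pig 18 the macrophage mean was 0.28 (camera adjusted p = 0.0764), oxidative phosphorylation -0.22 (0.1) and fatty acid oxidation -0.28. The 6 mesothelium and epicardium genes averaged 1.09, with keratin 8 (KRT8) at 2.37 ± 0.58, TBX18 at 0.95 ± 0.27 and keratin 18 (KRT18) at 2.19 ± 0.76, 3 genes past when adjusted over the list alone. KRT8 and KRT18 fell short without pig 10 (1.59 and 1.16), KRT18 without pig 16 and TBX18 without pig 18, where KRT18 read 3.42. That list had a camera adjusted p of 0.00277, adjusted p = 0.363 with an estimated correlation. With 1 score per array, the exact sign-flip p was 0.0312 for endothelial genes (lower in 6 of 6 pigs), 0.0625 for oxidative phosphorylation (lower in 5 of 6) and 0.0938 for interferon and mesothelium genes (higher in 5 of 6). It was 0.125 for TCA cycle and fatty acid oxidation (lower in 4 of 6) and 0.344 for macrophage genes (higher in 4 of 6), and none passed when adjusted over the lists (0.344 to 0.567). The sarcomere (-0.335) and ion channel (-0.321) scores were also lower in 6 of 6 pigs. Each had an exact sign-flip p of 0.0312, and 0.344 adjusted over the lists. Of the 33 lists fry called 3 between border zone and normal region, where camera called 16. The low muscle transcripts of pig 40 were in its infarct core; without that pig the muscle and energy means here were -0.49 for fatty acid oxidation, -0.49 for TCA cycle and -0.49 for oxidative phosphorylation.

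The border count is fragile. Limma called 0 probes with scan series as a covariate (5320 at an unadjusted p under 0.05) and 0 with slide as a block (4033), 1 with pig as a fixed block, 333 within scan series 1 and 3 within scan series 2; leaving out pigs gave 0 without pig 16 or pig 40, 1 without pig 10, 19 without pig 18, 21 without pig 12, 97 without pig 14, 234 without pig 15 and 269 without pig 11.

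The third region comparison sets the infarct core against the border zone within the same 9 pigs (9 and 9 arrays). The core again had more scar and macrophage transcripts and fewer of muscle and mitochondria. Limma called 7919 probes higher and 8125 lower, which covers 1650 and 1672 genes, 609 and 571 of them more than 2-fold. ACP5, the tartrate-resistant phosphatase of osteoclasts and macrophages, rose by 4.07 ± 0.34, lysozyme by 3.81 ± 0.37 and CHI3L1, a secreted chitinase-like protein, by 3.69 ± 0.47, each in 9 of 9 pigs.

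All 28 scar matrix genes rose again, by 1.87 on average (1.49 and 2.38 within scan series 1 and 2), and all 23 fatty acid oxidation genes (mean -1.59), 17 TCA cycle genes (-1.58), 16 oxidative phosphorylation genes (-1.59) and 19 sarcomere genes (-2.03) fell. The sarcomere mean was -2.44 within scan series 1, -1.36 within scan series 2 and -1.30 without pig 40, whose infarct core had the low muscle score. Within scan series 1 and 2 the energy means were -1.65 and -1.54, -1.64 and -1.57, and -1.73 and -1.44. Phospholamban (PLN), the brake on the calcium pump, fell by 2.46 ± 0.40 and telethonin (TCAP), a titin cap protein, by 2.33 ± 0.41. Of 17 macrophage genes 15 rose (mean 1.27), of 24 proteases and inhibitors 20 rose and 1 fell (1.09), and of 35 inflammatory genes 22 rose and 1 fell (0.84). Gelatinase B (MMP9) was up by 3.56 ± 0.43, GPNMB, a glycoprotein of lipid-loaded macrophages, by 2.88 ± 0.40 and ICAM1, an adhesion molecule for leukocytes, by 0.97 ± 0.14. Camera adjusted p for these 8 lists ranged from 1.4e-10 to 5.09e-06, and the lists had adjusted p = 0.285 to adjusted p = 0.328 with an estimated correlation.

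The other genes with the highest rises were ACAN (3.91 ± 0.57), COL11A1 (3.57 ± 0.55), COLL11A1 (3.52 ± 0.54), the immunoglobulin A heavy chain IGHA (3.55 ± 0.39), PRSS35, a serine protease (3.35 ± 0.33), and macrophage elastase MMP12 (3.24 ± 0.73). The largest falls were in CCK (-3.69 ± 0.43), COX8H (-3.16 ± 0.56), ASB15 (-2.93 ± 0.44), TARSL2 (-2.87 ± 0.42), FITM1 (-2.80 ± 0.44), PGAM2, a muscle enzyme of glycolysis (-2.77 ± 0.43), PRKAG3, a subunit of AMP-activated kinase in muscle (-2.73 ± 0.47), KLHL31 (-2.70 ± 0.52), myoglobin (-2.69 ± 0.47) and KLHL41 (-2.68 ± 0.44). Of the fixed genes POSTN rose by 2.11 ± 0.46, IL1B by 1.47 ± 0.33 and CASP1 by 0.89 ± 0.17, and MYH7 (-1.13 ± 0.34), MYH6 (-1.51 ± 0.49), MEF2C (-0.66 ± 0.18), VEGFA (-1.25 ± 0.16) and the COL1A1 probe (-0.38 ± 0.13) fell. With slide as a block MYH7 no longer passed (limma adjusted p = 0.0527). Pig 40 carries much of several of these falls: without it MYH7 read -0.41, COX8H -2.06, KLHL31 -1.72 and myoglobin -1.74, and ACTA2 (-0.63, limma adjusted p = 0.052) and the COL1A1 probe (-0.27, 0.114) no longer passed. The probes of ACTA2 disagree here too, with -0.87 ± 0.24 for the brightest and 2.11 to 2.46 for 4 of 6 others. NPPA (0.56 ± 0.76), NPPB (0.39 ± 0.89), TNF (0.08 ± 0.21) and PECAM1 (0.16 ± 0.13) did not pass.

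Each of these 8 list scores moved the same way in 9 of 9 pigs, with an exact sign-flip p of 0.00391, the smallest that 9 pigs allow, and 0.00758 adjusted over the lists. Limma's probe count was 5667 within scan series 2 alone and 9223 with no pig block.

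The treatment question, whether injected secretome changed gene expression against medium, was asked first in the infarct core (6 secretome and 3 medium arrays). Limma called 0 probes higher and 5 lower of 34360, with 1682 at an unadjusted p under 0.05. SERPINE3, a member of the serine protease inhibitor family, differed by -3.69 ± 0.60 on the log2 scale, with a mean level of -5.30 ± 0.72 (SD, n = 6) with secretome and -1.62 ± 0.48 (SD, n = 3) with medium. Claudin 3 (CLDN3), a tight junction protein of epithelia, differed by -2.56 ± 0.43, from -1.30 ± 0.58 with medium to -3.86 ± 0.38 with secretome. Both had a limma adjusted p of 0.0470, 0.00539 with scan series as a covariate and 0.594 with slide as a block. Normal region arrays of both arms read -6.06 to -4.71 for SERPINE3 and -4.52 to -3.91 for CLDN3. The secretome infarct cores lay near that level (-6.51 to -4.37 and -4.53 to -3.49), and the 3 medium infarct cores lay above it. SERPINE3 passed only without pig 10 and fell short without pig 18 (0.0537), 13 (0.115), 15 (0.161), 11 (0.187), 16 (0.193), 12 (0.212), 14 (0.223) or 40 (0.874). CLDN3 fell short without pig 13 (0.154), 15 (0.167), 16 (0.193), 11 (0.211), 12 (0.212), 14 (0.225) or 40 (0.874). The other called probes, named because the count is 5, were a GSTA1 probe (-3.40 ± 0.54), not the brightest of that glutathione transferase, and 2 probes without a gene symbol (-3.75 ± 0.59 and -3.68 ± 0.62).

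The next genes did not pass. On the lower side RPTN, an epidermal matrix protein, read -4.98 ± 0.98, ALOX15, a lipoxygenase whose probe is described as ALOX12, -2.88 ± 0.63, and IRG1, the itaconate-forming enzyme of activated macrophages, at least 2.17-fold lower. Their limma adjusted p was 0.182 (0.0172 for RPTN without pig 18), 0.403 and 0.348, and 0.0135, 0.0445 and 0.0223 with scan series as a covariate. On the higher side MTRF1 read 1.22 ± 0.34, PPP2R2B 1.17 ± 0.34, insulin-like growth factor 2 (IGF2) 1.5 ± 0.49, the prion protein gene PRNP 0.52 ± 0.17 and SPAG11B 0.74 ± 0.25, with limma adjusted p of 0.836 to 0.974. MYH7 read 1.61 ± 0.72 (limma adjusted p = 0.974), with 8.46 ± 2.55 (SD, n = 3) for medium, where pig 40 stood at 5.54, and 10.07 ± 0.64 (SD, n = 6) for secretome; without pig 40 the difference was 0.15. CASP1 read -0.98 ± 0.36, IL1B -0.80 ± 0.70, TNF -0.51 ± 0.44, POSTN -0.24 ± 0.96, the COL1A1 probe -0.10 ± 0.27, MYH6 0.90 ± 1.04, NPPA 1.55 ± 1.60, NPPB 1.77 ± 1.87, MEF2C 0.63 ± 0.38, ACTA2 0.86 ± 0.51, VEGFA 0.56 ± 0.33 and PECAM1 0.47 ± 0.28.

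Immune lists were lower and muscle lists higher with secretome in camera. Of 18 T and NK cell genes 18 lay below 0 (mean -1.24, and -1.28 and -0.71 within scan series 1 and 2), such as KLRK1, an activating NK receptor (-1.78 ± 0.69), CD2, a T cell adhesion molecule (-1.60 ± 0.63), and FOXP3, the factor of regulatory T cells (-1.20 ± 0.47). Of 21 antigen presentation genes 20 lay below 0 (mean -0.61, and -0.89 and -0.23 within scan series), such as PSMB9 of the immunoproteasome (-0.84 ± 0.31) and the class I gene SLA-3 (-0.72 ± 0.26). Macrophage genes averaged -0.70 (-0.72 and -0.71 within scan series), with C1QA, a chain of complement C1q, at -1.09 ± 0.37, and inflammatory genes averaged -0.50 (-0.58 and -0.28), with the chemokine CXCL9 at -2.03 ± 0.67. Without pig 40 antigen presentation averaged -0.39 and inflammatory genes -0.32. Camera adjusted p was 1.01e-10, 2.44e-11, 1.1e-07 and 8.36e-06. The macrophage list had adjusted p = 0.264 with an estimated correlation, and the other 3 had adjusted p = 0.143 with an estimated correlation. No member passed, either over all probes or adjusted over the list alone. In this comparison fry called 0 of 33 lists, where camera called 20. The exact permutation p of the scores was 0.0476, 0.0476, 0.0357 and 0.0119, and 0.157 to 0.196 adjusted over 33 lists.

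The sarcomere list averaged 1.79 higher with secretome, with 19 of 19 members above 0, such as the calcium release channel RYR2 (2.23 ± 0.85) and alpha actinin 2 (ACTN2) of the Z disc (2.38 ± 0.95). Fatty acid oxidation averaged 0.90, TCA cycle 0.85 and oxidative phosphorylation 0.80, with the mitochondrial regulator PPARGC1A at 2.12 ± 0.87 and the ketone enzyme OXCT1 at 1.36 ± 0.52. Camera adjusted p ran from 3.83e-13 to 1.31e-07; the sarcomere list had adjusted p = 0.264 with an estimated correlation and the energy lists adjusted p = 0.277 with an estimated correlation. Exact permutation p was 0.202 to 0.226. The low muscle score of the pig 40 medium sample moves with this group: without pig 40 the means were 0.28, 0.33, 0.32 and 0.33, and with slide as a block 0.41, 0.24, 0.21 and -0.18. Within scan series 1 and 2 the sarcomere means were 2.04 and 0.65.

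The count of 5 rests on single animals and on the fit. Limma gave 18 probes with scan series as a covariate, 0 with slide as a block (2742 at an unadjusted p under 0.05), 13 within scan series 1 and 36 within scan series 2; leaving out pigs gave 0 without any 1 of pigs 11, 12, 14, 15, 16 and 40, 1 without pig 13, 10 without pig 18 and 11 without pig 10.

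**Figure D4:**
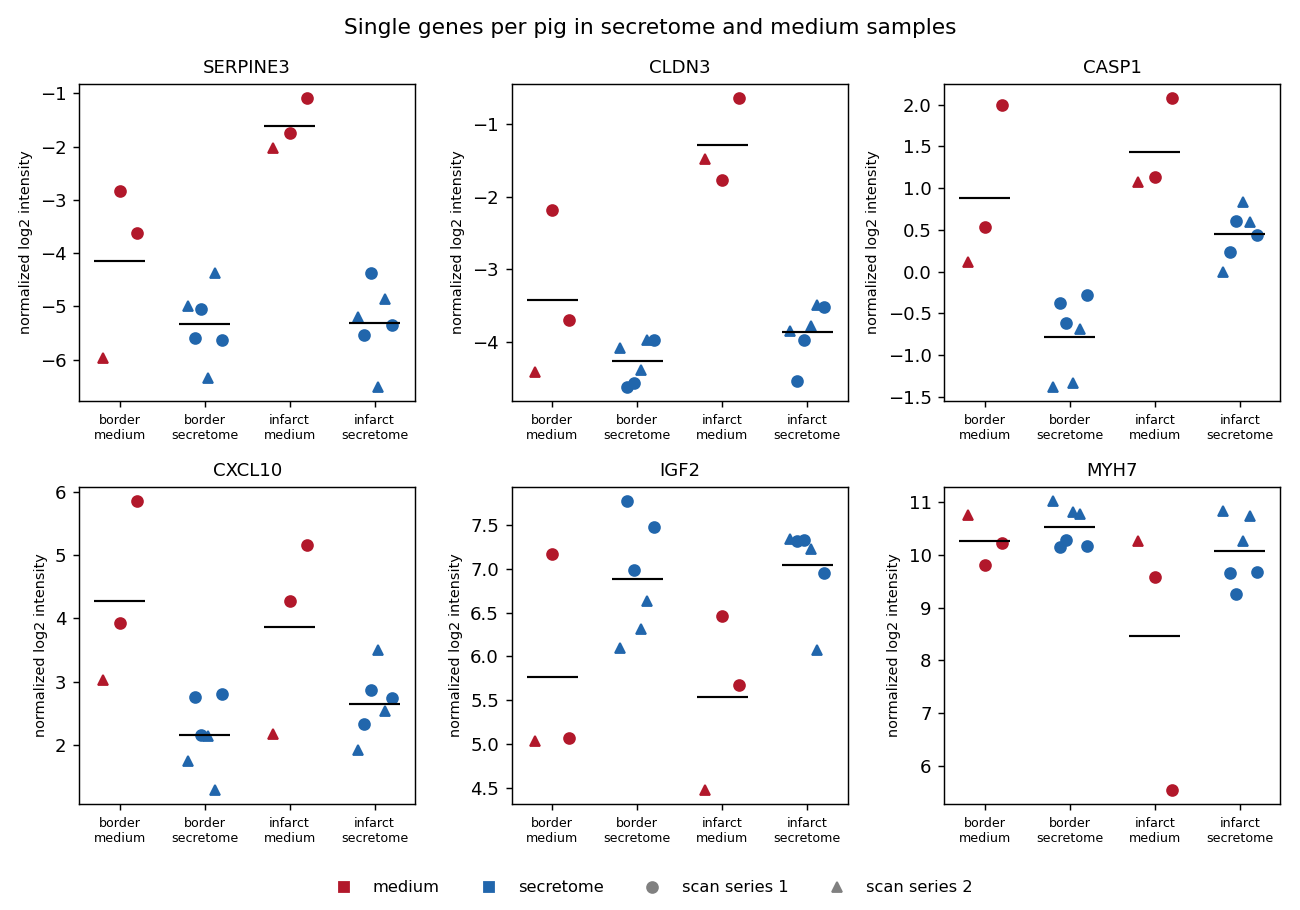
Normalized log2 intensity of 6 genes in border zone and infarct core, 1 point per pig, coloured by arm and shaped by scan series, with bars at group means. SERPINE3 and CLDN3 are lower in all 6 secretome than in all 3 medium infarct cores, and the pig 40 medium infarct core has the lowest MYH7, 5.54.

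In the border zone (6 secretome and 3 medium arrays) limma called 0 probes, with 2474 at an unadjusted p under 0.05 and a smallest adjusted p of 0.103. The medium array of pig 40 here had the lowest share of probes well above background of all arrays (61.51%). It also enters the average over infarct core and border zone. Of the lower genes, those with the smallest p were the chemokines CXCL11 (-2.81 ± 0.68) and CXCL10 (-2.12 ± 0.54), which attract T cells and read -1.76 and -1.33 without medium pig 40, NCR3, an activating NK receptor (-1.75 ± 0.45), CASP1 (-1.66 ± 0.36, and -1.11 without pig 40) and MPZL3 (at least 1.22-fold lower). Of the higher genes they were FCN2, a lectin of the complement system (3.06 ± 0.84), ARFGEF3 (1.86 ± 0.51), MTMR7, a lipid phosphatase (1.48 ± 0.35), KLF11, a zinc finger factor (1.33 ± 0.31), and ATIC, an enzyme of purine synthesis (0.65 ± 0.17). None passed, with limma adjusted p of 0.103 for MPZL3 and 0.663 for the other 9; MPZL3 passed with scan series as a covariate (0.0104) and without pig 16 (0.0464). Of the fixed genes NPPB read -3.02 ± 1.87, POSTN -1.70 ± 0.96, IL1B -1.52 ± 0.70, MYH6 2.08 ± 1.04 and PECAM1 0.60 ± 0.28. MYH7 (0.28 ± 0.72), NPPA (0.22 ± 1.60), MEF2C (0.42 ± 0.38), ACTA2 (0.24 ± 0.51), TNF (-0.23 ± 0.44), VEGFA (0.46 ± 0.33) and the COL1A1 probe (-0.07 ± 0.27) did not pass either.

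Immune lists were again lower. Macrophage genes averaged -0.90 with 17 of 17 below 0 (-0.85 and -0.84 within scan series 1 and 2), and T and NK cell genes -1.30 with 16 of 18 below 0 (-1.64 and -0.46). Adjusted over the list alone, 4 macrophage genes fell, CD86 (-1.07 ± 0.28), the Fc receptor FCGR1A (-1.23 ± 0.41), AIF1 (-1.12 ± 0.37) and GPNMB (-2.42 ± 0.84), and 7 T and NK cell genes fell, among them the T cell receptor chains CD3G (-2.26 ± 0.62) and CD3D (-2.02 ± 0.58). Interferon response averaged -0.58 (-0.72 and -0.16), antigen presentation -0.43 (-0.53 and -0.36) and inflammatory genes -0.68 (-0.75 and -0.38), where B2M, the light chain of class I molecules (-0.79 ± 0.23), SLA-DOB (-1.20 ± 0.34) and CXCL9 (-2.62 ± 0.67) fell adjusted over the list alone. Without pig 18 or pig 40 no macrophage, T and NK cell, antigen presentation or inflammatory gene passed in that way. Macrophage genes past were 0 without pig 13, 1 without pig 11 or 14, 2 without pig 15, 6 without pig 10 or 12 and 9 without pig 16, and T and NK cell genes 4 without any 1 of pigs 11 to 15. Antigen presentation had 0 without any 1 of pigs 11, 13, 14 and 15, and inflammatory genes 0 without pig 15 and 4 without pig 10. Without pig 40 CXCL9 read -1.58, AIF1 -0.61 and B2M -0.45, and without pig 18 the interferon mean was -0.29 (camera adjusted p = 0.136). Camera adjusted p for these 5 lists ran from 9.35e-08 to 6.71e-05; macrophage, T and NK cell and inflammatory genes had adjusted p = 0.290 with an estimated correlation, and interferon and antigen presentation genes adjusted p = 0.435 with an estimated correlation. Exact permutation p of the scores was 0.0238 for macrophage and T and NK cell genes, 0.0357 for antigen presentation and 0.0476 for interferon and inflammatory genes, each 0.224 adjusted over 33 lists.

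Scar matrix genes averaged -0.87 (-0.35 and -1.42 within scan series), endothelial genes 0.62 with 13 of 13 above 0 (0.56 and 0.32), and fatty acid oxidation genes 0.65 (0.65 and 0.31). Scar matrix was -0.54 without pig 11 and fell short without pig 18 (-0.69, camera adjusted p = 0.0508), endothelial genes were 0.98 without pig 10 and fell short without pig 40 (0.18, 0.12), and fatty acid oxidation was 0.99 without pig 10 and 0.43 without pig 18. Fibronectin read -1.74 ± 0.73, PROX1, a factor of lymphatic endothelium, 1.37 ± 0.52, NOS3, the endothelial nitric oxide synthase, 0.94 ± 0.37 and the uncoupling protein UCP3 2.01 ± 0.76, none past the threshold. Camera adjusted p was 0.000101, 0.000333 and 0.000375; scar matrix and fatty acid oxidation had adjusted p = 0.631 with an estimated correlation and endothelial genes adjusted p = 0.435 with an estimated correlation. Exact permutation p was 0.274, 0.155 and 0.119. In the border zone fry called 0 of 33 lists for secretome, where camera called 13. Limma called 4 probes with scan series as a covariate and 4 with slide as a block, 2 within scan series 1 and 8 within scan series 2, and 3 without pig 16 and 1 without pig 18.

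In the normal region (4 secretome and 2 medium arrays) limma called 0 probes, with 596 at an unadjusted p under 0.05 and a smallest adjusted p of 0.414. FCN2 read 3.94 ± 0.96, BEST1, a chloride channel, 1.72 ± 0.48, MOXD1 1.89 ± 0.54, PEG10 1.33 ± 0.37 and ALDH1L2, a mitochondrial folate enzyme, 1.26 ± 0.37. OASL, an interferon-induced gene, read -2.58 ± 0.84 and TMEM108 -1.20 ± 0.37, and CYLC1, CHI3L2 and KCND2 were at least 1.79-fold, 2.18-fold and 2.86-fold lower. No fixed gene passed: their values ran from -0.58 ± 0.41 (CASP1) to 1.14 ± 1.19 (MYH6). The interferon response list averaged -0.34 (-0.89 and 0.22 within scan series 1 and 2), antigen presentation -0.22, T and NK cell genes -0.51, ribosomal proteins -0.18, scar matrix 0.69 and endothelial genes 0.37, with camera adjusted p of 0.000103 to 0.0150. Through the pig block these fitted means also draw on the other regions, and so on pigs without a normal region array. On the normal region arrays alone, mean ribosomal scores were 7.899 with secretome and 7.889 with medium, the opposite direction. Antigen presentation scores were 3.176 and 3.211, and T and NK cell scores -2.86 and -2.552. Scar matrix had adjusted p = 0.731 with an estimated correlation and the other 5 lists adjusted p = 0.712 with an estimated correlation. The 22 apoptosis genes averaged -0.15 (camera adjusted p = 0.0301, adjusted p = 0.273 with an estimated correlation) and the 35 inflammatory genes -0.21 (0.0387, adjusted p = 0.712 with an estimated correlation). Each of these 8 list calls ends without some single pig. Without pig 18 interferon response was -0.05 (camera adjusted p = 0.447) and endothelial genes 0.25 (0.145). Without pig 10 antigen presentation was -0.01 (0.598), T and NK cell genes -0.30 (0.29), ribosomal proteins -0.11 (0.216) and scar matrix 0.81 (0.145). Scar matrix also fell short without pig 15 (0.172), antigen presentation without pig 16 (-0.12, 0.0748), and ribosomal proteins and endothelial genes without pig 40 (-0.03 and 0.14, 0.288 and 0.275). Apoptosis genes fell short without pig 10, 15, 16, 18 or 40 (0.0663 to 0.188; -0.09 without pig 40), and inflammatory genes without pig 10, 11, 13, 16 or 40 (0.0669 to 0.339; -0.13, -0.13 and -0.09 without pigs 10, 16 and 40). Larger without pig 18 were antigen presentation (-0.50), T and NK cell (-0.90), ribosomal (-0.39) and inflammatory genes (-0.40), and without pig 10 interferon (-0.67) and endothelial genes (0.72); T and NK cell genes were -0.34 without pig 40. Exact permutation p of the 8 scores was at least 0.200, and 15 splits of 6 pigs cannot give less than 0.0667. In the normal region fry called 0 of 33 lists for secretome, where camera called 9. With slide as a block the T and NK cell mean was 0.15; limma called 1 probe in that fit, 17 within scan series 2 and 2 without pig 18.

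Averaged over infarct core and border zone (6 secretome and 3 medium pigs), limma called 0 probes, with 1875 at an unadjusted p under 0.05 and a smallest adjusted p of 0.233. Immune lists were lower with secretome, and the smallest exact permutation p, 0.0119, was that of the 6 inflammasome genes (mean -0.73). T and NK cell genes averaged -1.27 with 18 of 18 below 0 (-1.46 and -0.58 within scan series 1 and 2), macrophage genes -0.80 with 17 of 17 below 0 (-0.78 and -0.77), antigen presentation genes -0.52 with 20 of 21 below 0 (-0.71 and -0.30) and inflammatory genes -0.59 with 31 of 35 below 0 (-0.67 and -0.33).

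Adjusted over the list alone, 8 T and NK cell genes fell, among them CD2 (-1.91 ± 0.56), KLRK1 (-2.04 ± 0.61) and CD3G (-1.82 ± 0.55), 6 antigen presentation genes fell, among them B2M (-0.66 ± 0.20), 1 macrophage gene fell, CD86 (-0.88 ± 0.25), and 2 inflammatory genes fell, CXCL9 (-2.33 ± 0.59) and CXCL10 (-1.67 ± 0.47). Without pig 40 none of these genes passed, and CXCL9 read -1.33, CXCL10 -0.95 and B2M -0.40. For T and NK cell genes the number past was 0 without pig 15 or 18, 4 without pig 13, 5 without pig 12, 12 without pig 10 and 13 without pig 16. For antigen presentation it was 0 without any 1 of pigs 11 to 15, 2 without pig 18 and 4 without pig 10 or 16. For inflammatory genes it was 0 without pig 11, 13, 15 or 18 and 5 without pig 10, and for macrophage genes 0 without pig 13, 15 or 18, 3 without pig 10, 9 without pig 12 and 8 without pig 16. Camera adjusted p was 8.31e-11, 1.35e-09, 1.35e-09 and 1.23e-06. T and NK cell and inflammatory genes had adjusted p = 0.132 with an estimated correlation, and macrophage and antigen presentation genes adjusted p = 0.188 with an estimated correlation. Exact permutation p was 0.0238 for each of the 4 scores, 0.0982 adjusted over 33 lists, 0.05 when arms were permuted within scan series, and 0.0714 to 0.107 without pig 40. Fry gave adjusted p of 0.0434 for T and NK cell and inflammatory genes and 0.0648 for the other pair, and with scan series as a covariate 0.00645 to 0.0118. Without that covariate fry called 3 of 33 lists for the average, where camera called 17. For secretome in the infarct core, border zone or normal region alone it called 0, where camera called 20, 13 and 9. For infarct core against normal region, and against border zone, it called 25 each.

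The interferon response list averaged -0.49 (-0.77 and 0.13 within scan series), with IFNG, the type II interferon, at -1.18 ± 0.34 and past when adjusted over the list alone, though not without any 1 of pigs 11, 12, 13, 15 and 40 (-0.75 without pig 40). The interferon mean was -0.84 without pig 10 and -0.19 without pig 18 (camera adjusted p = 0.221). On the higher side fatty acid oxidation averaged 0.77 with 23 of 23 above 0, TCA cycle 0.74 and sarcomere genes 1.13, where the titin-linked LDB3 read 1.81 ± 0.87. Without pig 40, whose infarct core had the low muscle score, these means were 0.43, 0.39 and 0.34, and without pig 10 TCA cycle and sarcomere genes were 1.12 and 1.76. Camera adjusted p for these 4 lists ran from 1.05e-07 to 1.23e-06; interferon genes had adjusted p = 0.402 with an estimated correlation and the others adjusted p = 0.422 with an estimated correlation. Exact permutation p was 0.0952 to 0.155.

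Among single genes averaged over both regions, SERPINE3 (-2.44 ± 0.53), CLDN3 (-1.70 ± 0.38), NCR3 (-1.76 ± 0.39), CASP1 (-1.32 ± 0.32) and MPZL3 (at least 1.42-fold lower) had the smallest p of the lower genes. MTMR7 (1.15 ± 0.31), KLF11 (1.01 ± 0.28), MTRF1 (1.07 ± 0.30), ARFGEF3 (1.57 ± 0.45) and CYP27A1, a sterol hydroxylase (1.67 ± 0.50), had those of the higher genes. None passed in limma (adjusted p 0.402 to 0.809), and with scan series as a covariate SERPINE3 (0.02), CLDN3 (0.0199), CASP1 (0.0431) and MPZL3 (0.0134) did. Without pig 10 SERPINE3, NCR3 and CYP27A1 passed (each 0.0393), and without pig 40 CASP1 read -0.88 and MYH7 0.21. No fixed gene other than CASP1 passed in either fit, with MYH7 at 0.94 ± 0.63 and IL1B at -1.16 ± 0.62. Limma called 54 probes with scan series as a covariate, 17 higher and 37 lower, 5 with slide as a block, 15 within scan series 1, 44 within scan series 2, 41 without pig 10 and 1 without pig 16 or pig 18.

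**Figure D5:**
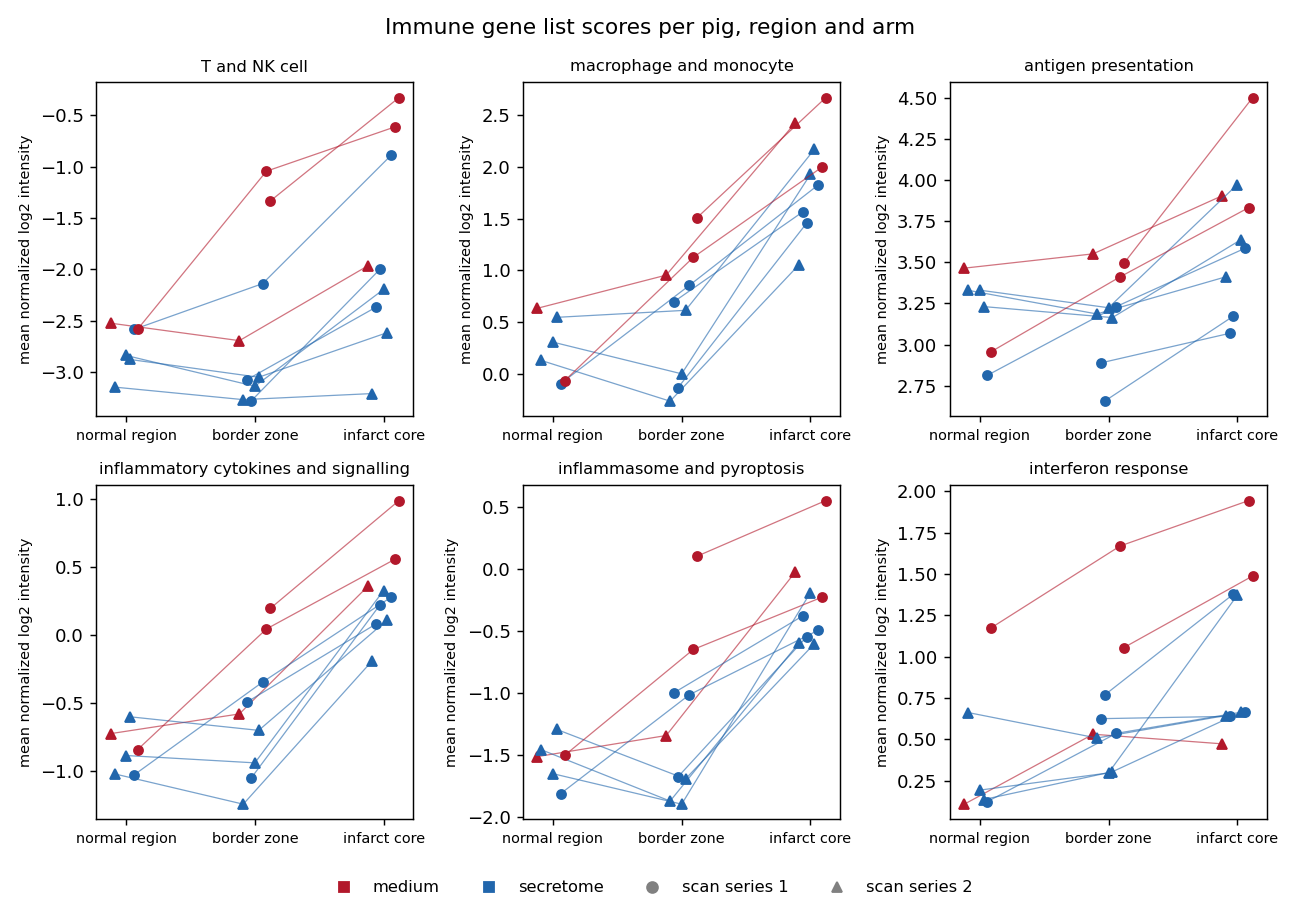
Mean normalized log2 intensity of 6 immune gene lists in the normal region, border zone and infarct core, 1 point per array and 1 line per pig, coloured by arm and shaped by scan series. In the border zone and infarct core the mean T and NK cell scores are -1.69 and -0.97 with medium and -2.99 and -2.21 with secretome, with overlap between single pigs.

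Whether the secretome difference itself changed from region to region was tested as a difference of differences. Limma called 0 probes for infarct core minus normal region (1168 at an unadjusted p under 0.05), 0 for border zone minus normal region (1665) and 0 for infarct core minus border zone (1878). The smallest adjusted p values were 0.166, 0.386 and 0.513. Without pig 18, 1 of 2 medium pigs with a normal region, the counts were 11, 5 and 4 probes, and without pig 10 the first was 7; without pig 13 the first and second were 1 each.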

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

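The tests of mesothelial genes and of slide for the SERPINE3 group, the counts of splits balanced over scan series, and the choice of the 8 lists with the smallest p per difference below, were made only after the values were seen.

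Of 183 groups of 4 to 10 samples, 13 had a sample far from the others, where chance gives about 1 in 20 groups, or 9.2. In the infarct core with secretome, pig 14 stood out in matrix proteases (1.81, nearest 1.39), while the medium infarct cores ran from 1.547 to 1.86. In the border zone with secretome, pig 16 stood out in T and NK cell genes (-2.14, nearest -3.05) and pig 11 in apoptosis genes (1.15, nearest 0.95). In the normal region with secretome, pig 11 stood out in interferon response genes (0.66, nearest 0.19) and pig 16 in the percent of probes well above background (72.36, nearest 66.11). Between infarct core and normal region within pigs, pig 15 had a small collagen rise (1.41, nearest 3.40) and pig 11 a ribosomal difference of 0.08 (nearest -0.10). Between border zone and normal region, MYH7 of pig 18 read -0.60 (nearest -0.23). Between infarct core and border zone, pig 40 stood out in sarcomere genes (-5.61, nearest -2.43), ribosomal genes (-1.49, nearest -0.27) and MYH7 (-4.69, nearest -1.04), pig 15 in MYH6 (-4.56, nearest -2.52) and pig 11 in MEF2C (0.30, nearest -0.44). The ribosomal difference of pig 40 lies in its border zone array. The highest ribosomal score of the medium border zones was 9.087, against 7.478 to 7.903 in medium infarct cores and 7.69 to 8.05 in secretome border zones. Medium groups, of 2 or 3 arrays, were too small for this check.

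Camera tests of the difference between 2 regions' secretome differences passed for 18 lists (infarct core minus normal region), 9 (border zone minus normal region) and 5 (infarct core minus border zone), and for 0 with an estimated correlation. For infarct core minus normal region these were sarcomere genes (1.30, adjusted p = 3.97e-09), oxidative phosphorylation (0.76), fatty acid oxidation (0.69), TCA cycle (0.66), ribosomal proteins (0.25), matrix proteases (-0.60), antigen presentation (-0.38) and T and NK cell genes (-0.73), each with adjusted p = 0.454 with an estimated correlation. For border zone minus normal region they were collagen (-1.56, adjusted p = 4.24e-12), macrophage genes (-0.70), T and NK cell genes (-0.79), fatty acid oxidation (0.43), TCA cycle (0.43), cardiac transcription factors (0.48), cartilage and bone genes (-1.07) and inflammatory genes (-0.47), each with adjusted p = 0.704 with an estimated correlation. For infarct core minus border zone they were ribosomal proteins (0.39), sarcomere genes (1.33), cardiac stress genes (1.76), collagen (0.79) and oxidative phosphorylation (0.47), each with adjusted p = 0.891 with an estimated correlation. Without pig 40, infarct core minus normal region was 0.35 for sarcomere genes, 0.42 for oxidative phosphorylation, 0.37 for fatty acid oxidation, 0.39 for TCA cycle, 0.07 for ribosomal proteins and -0.24 for antigen presentation. Infarct core minus border zone was then -0.13 for sarcomere genes, -0.11 for ribosomal proteins, 0.47 for cardiac stress genes and -0.10 for oxidative phosphorylation, so 3 of these 4 changed sign; collagen was 0.95.

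The sarcomere list was 1.79 ± 1.15 higher in the infarct core with secretome. Without pig 40 it was 0.28 ± 0.74, so the single medium sample with few muscle transcripts is a candidate explanation for most of it. Within scan series it was 1.51 ± 1.08, a spread too wide to tell scan series apart from treatment. Whether that sample held more scar was not tested.

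The mean of the T and NK cell, macrophage, antigen presentation and inflammatory lists was -0.80 ± 0.22 with secretome over infarct core and border zone (exact permutation p = 0.0238). Within scan series it was -0.75 ± 0.21, which argues against scan series as the whole cause. With the part that goes with the collagen score removed it was -0.64 ± 0.21 (exact permutation p = 0.0238). This argues against less scar as the whole cause only as far as the collagen score measures scar. In the infarct core that score hardly differed between arms (3.968 with medium, 3.888 with secretome). Sarcomere genes averaged 1.13 higher with secretome (0.34 without pig 40) and were not used in the correction, so a smaller scar share by that measure stays open. Without pig 40 it was -0.63 ± 0.24, and with 2 medium pigs left that pig's share stays open. An effect of the secretome may remain as a hypothesis, found and tested on the same 9 pigs.

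SERPINE3, CLDN3, a GSTA1 probe and 2 probes without a symbol were lower in the infarct core with secretome than with medium, with a mean of -3.41. The root mean square of the standard errors of the single probes was 0.56. These 5 probes were picked because they passed in this same comparison, so their mean is not an independent measure of its size. With slide as a block the mean was -2.71 (root mean square of the standard errors 0.80), and the calls ended (limma adjusted p = 0.594). Of 6 slides 0 held infarct core arrays of both arms, so slide cannot be told apart from treatment there and stays open. Mesothelial cells in the medium samples were tested as a candidate source, since CLDN3 is an epithelial gene; no list ties the 5 probes together. The 5 mesothelium and epicardium members other than UPK1B differed by 0.02 ± 0.27 (exact permutation p = 0.869), which leaves this open since the members go both ways. Of the 6 list members 4 were lower, 4 were well above background on all normal region arrays and 0 are in another list. UPK1B read -3.94, WT1 -1.08, KRT8 -0.67, TBX18 -0.24, TCF21 0.01 and KRT18 2.10.

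Shuffled labels were fitted for each count. Infarct core against normal region called 18207 probes, and 1 of 100 draws of region labels within pigs gave as many, the real one included (highest other 7993). For infarct core against border zone it was 1 of 100 (16044, highest other 11540), so chance can be excluded for both. For border zone against normal region 6 of 100 draws gave as many as 160 (highest other 14974). These draws exchange infarct labels too and so carry the infarct core difference; they do not decide whether chance gives the border count, which stays open. For secretome in the infarct core 7 of 84 splits gave at least 5 probes (highest other 9501). The 6 others all put the 3 medium labels in 1 scan series, and of the 40 splits balanced over scan series like the real one 1 did (highest other 2). Over all splits chance stays open, and the place of the high counts points to the scan series. For the border zone (0 probes, 6211), the average (0, 10336) and infarct core minus border zone (0, 794) 84 of 84 splits gave as many. Every split reaches a real count of 0, so these shares could not come out otherwise and decide nothing. For the average, splits with all 3 medium labels in 1 scan series reached 10336 and others at most 19, which points to the scan series there. The 794 came from a split that labels pigs of both scan series as medium (pigs 11, 13 and 14), which called 110 probes in the border zone. With scan series as a covariate the average called 54 probes, and 1 of 40 splits balanced over scan series gave as many (highest other 36), though over all 84 splits 5 did (highest other 171). In the infarct core that fit called 18, but 74 in a balanced split (pigs 12, 13 and 14 as medium) and 591 in another split (pigs 10, 14 and 40). In the border zone the real 4 was matched by a balanced split (pigs 14, 16 and 40), and the split of pigs 11, 13 and 14 gave 585.

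Camera with the preset correlation also calls many lists when pigs are split in other ways. For secretome as many lists as the real ones were past in 4 of 84 splits in the infarct core (20, highest other 20), 19 of 84 in the border zone (13, highest other 18), 11 of 84 for the average (17, highest other 20) and 76 of 84 for infarct core minus border zone (5, highest other 18). In the infarct core 3 other splits tied with the real 20, and the counts were not adjusted for each other, so this share gives weak evidence at most. Chance cannot be excluded for the other secretome counts. For the regions, as many lists as the real 19, 16 and 19 were past in 19, 39 and 24 of 100 draws for infarct core against normal region, border zone against normal region and infarct core against border zone (highest other 21 each). These draws carry the infarct core difference too, so they do not show what camera calls without one, and chance stays open for the region list counts.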

How the results depend on the processing

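Chosen only after the data were seen were the fixed pig block within each scan series, leaving out single arrays of pig 40, leaving out pigs with scan series as a covariate, permutation within scan series, list scores without pig 40, fry with scan series as a covariate and adjustment over the list alone without each pig. Of the values for single genes under alternatives 2808 kept direction and side of the threshold, 152 fell short of it, 21 newly passed, 119 moved and 13 reversed; for lists these were 931 the same, 186 short of it and 3 reversed. The cause was not tested unless stated.

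Probes called between infarct core and normal region (18207) ran from 14601 to 19607 with 1 pig left out, with or without scan series as a covariate; border zone against normal region (160) from 0 to 269; infarct core against border zone (16044) from 12907 to 17675. For secretome the ranges were 0 to 86 in the infarct core (5), 0 to 28 in the border zone (0), 0 to 17 in the normal region (0) and 0 to 320 averaged (0). For the differences between regions they were 0 to 11 (infarct core minus normal region), 0 to 5 (border zone minus normal region) and 0 to 4 (infarct core minus border zone), each from 0. Where an arm is left with 1 sample of a region, it is assumed to vary like the other groups.

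With scan series as a covariate border zone against normal region gave 0 probes and secretome 18 in the infarct core, 4 in the border zone and 54 averaged. With slide as a block these were 0, 0, 4 and 5, with 1 in the normal region; oxidative phosphorylation in the infarct core with secretome reversed to -0.18 and T and NK cell genes in the normal region to 0.15. Within scan series 1, with fewer arrays, they were 333, 13, 2 and 15. Within scan series 2 they were 3, 36, 8 and 44, with 17 in the normal region, 9719 between infarct core and normal region and 5667 between infarct core and border zone. With a fixed pig block the border zone gave 1 against the normal region, 0 in scan series 1 alone and 0 in scan series 2 alone, where infarct core against border zone gave 10111. Among the genes named in the report it ended the calls of MYH7 and NPPB between infarct core and normal region and of the genes the report names as called in the border zone, TNC, FN1, CILP and COMP among them, and changed no other gene call the report prints. With no pig block the border zone gave 0, infarct core against border zone 9223, and secretome 11, 2 and 48.

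Normexp with quantile scaling gave 0 for the border zone and 2 for secretome in the infarct core; the authors' values gave 0 and 2, with 1 for infarct core minus normal region, and ribosomal proteins in the normal region with secretome reversed to 0.028. Quantile scaling gave 0 for secretome in the infarct core and 1 in the border zone, and the percentile over detected probes 3 in the infarct core. No filter gave 96 for the border zone, and the filter on all arrays 73, with 0 for secretome in the infarct core. Array weights gave 943, and 126 in the infarct core, 10 averaged and 3 for infarct core minus normal region. The trended robust fit gave 0 for secretome in the infarct core. With only the arrays of the compared regions secretome gave 0 in the infarct core and 1 in the normal region. Without the infarct core array of pig 40 secretome gave 0 in the infarct core and infarct core minus normal region 1; without its border zone array the border zone gave 71 and secretome in the infarct core 0.

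Other probes of ACTA2 reversed its fall, to 2.52, 2.64, 0.50, 2.54, 1.11 and 2.18 between infarct core and normal region and 2.35, 2.46, 0.46, 2.35, 0.85 and 2.11 between infarct core and border zone. The other ELMSAN1 probe read -0.64. Adjusted p of SERPINE3 and CLDN3 ranged from 0.00142 to 0.904. Dim probes limit the bounds given as at least N-fold.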

Other observations

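Further gene groups moved between infarct core and normal region. Complement and coagulation genes averaged 1.10, with 19 of 26 higher and 5 lower, among them complement C2 (2.75 ± 0.29), C3 (1.94) and C6, of the membrane attack complex (at least 14.2-fold). Cartilage and bone genes averaged 2.15 with COMP (4.67), osteopontin SPP1 (4.82) and CILP (4.40), and TGF-beta family genes 0.80 with TGFB3 at 3.69 ± 0.43 and ID2 at 2.52. Cell cycle genes averaged 0.88 with TOP2A and CENPF at 1.58 each. Ion channel genes averaged -1.68 with the calcium channel subunit CACNB2 at -2.67 ± 0.38, and 8 of 8 cardiac transcription factors fell, with MYOCD at -1.94 and GATA4 at -1.02. Camera adjusted p for these lists ran from 0.000304 to 0.00347, and each had adjusted p = 0.307 with an estimated correlation except ion channels and cardiac transcription factors, adjusted p = 0.310 with an estimated correlation.

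Among the lists that did not pass camera between infarct core and normal region, 6 had a score that moved the same way in 6 of 6 pigs, with an exact sign-flip p of 0.0312 and 0.0448 adjusted over the lists. The mean score differences within these pigs, which leave out pig 40, were -0.507 for glycolysis and hypoxia, -0.483 for endothelial genes, -0.829 for skeletal muscle genes, -0.39 for red blood cell and platelet genes, 0.726 for cardiac stress genes and 0.0668 for apoptosis genes. With secretome averaged over infarct core and border zone, the 6 inflammasome genes averaged -0.73 (camera adjusted p = 0.00385, adjusted p = 0.210 with an estimated correlation), where CASP1 (-1.32 ± 0.32) and NLRP3, the sensor that activates it (-0.93 ± 0.28), fell adjusted over the list alone. The exact permutation p was 0.0119, the smallest that 84 splits allow, 0.0982 adjusted over 33 lists, 0.025 within scan series, and 0.0357 without pig 40, where the difference was -0.44.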
